A study of Homo sapiens with 6 samples.

How the data were processed

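The series measured total RNA from U-87 MG, an established human glioblastoma cell line, on 1-colour Affymetrix arrays. There were 3 arrays of cells exposed to electromagnetic fields and 3 arrays of unexposed cells, and per the labels each was an independent biological replicate. Groups were taken from the sample titles, which the source names match, while the description field of the exposed samples calls the cells both exposed and control. Per the labels' protocols, exposure began 24 h after seeding and ran without a break for 54 h, and dishes were allocated at random to a culture box inside a Faraday chamber (exposed) or to a box outside it (unexposed). The fields were aimed at 4 molecules: the microRNA miR-381, a mutated form of the alpha-kinase 2 gene, the heat shock protein HSP70 and the secreted glycoprotein CHI3L1.

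The deposited table holds 1 log2 expression value per probe set and array, summarised with RMA (robust multi-array average, which corrects background, normalizes between arrays and combines the probes of a probe set), per the submitters' processing notes. Those notes name Affymetrix Expression Console 3.0 and Transcriptome Analysis Console 3.0, and the further settings are not given in the sources used here. The log2 scale was also read from the values, which ran from 0.460 to 13.8 with array medians of 3.96 to 3.99. RMA makes the distributions of all arrays alike, so a change in the total amount of RNA per cell would not be visible in these values. The table has no detection calls and no read depth, and the number of arrays limits the precision. Genome coordinates were not used here.

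Of the 53617 probe sets, 16098 carried exactly 1 gene symbol in the platform annotation, 0 carried several and 37519 (the rest) were unnamed here. All 14884 symbols also stand in the RefSeq gene table of assembly GRCh38.p14, which was used for names alone, and members of gene lists were looked up under current and older symbols. Each of the 14884 genes was represented by the probe set with the highest mean over all 6 arrays. No probe set carried a name that marks Affymetrix controls, so the planned exclusion of control probe sets removed none and all 53617 were tested. The values of 1319 probe sets repeated those of another probe set.

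Differences were computed as exposed minus unexposed on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), without covariates and without a filter on dim probe sets. P-values were adjusted by the Benjamini-Hochberg method over all probe sets, and for genes over the representative probe sets of the same fit. The threshold was an adjusted p of 0.05. All adjusted p-values given for genes come from limma with this adjustment. Errors are standard errors (SE) of the log2 change from the fit, group values are means ± SD, and intervals are 95% intervals. Figures were drawn with matplotlib 3.10.9.

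Before the data were examined, 38 gene lists were fixed, covering the study's targets, stress responses, cell division, metabolism, signalling, glioma biology and markers of other cell types. Of the 777 list entries 448 were measured, and several lists lack central members, so each result concerns a list's measured members alone. The 35 lists with at least 3 measured members were tested with limma's camera at its preset inter-gene correlation of 0.01, which compares a list with all other genes. Beside it stand camera with an estimated correlation and fry, which asks whether a list's members move one way on balance without comparing them with other genes. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. Lists about the molecules named above, their locus or their reported targets were chosen from the study's own description, but not from its measurements.

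The genes named in the text were chosen by a rule set in advance. It takes, among genes past the threshold whose 3 exposed values all lie on one side of the 3 unexposed values, the 12 with the largest and the 12 with the smallest log2 change, passing over symbols that are only a clone, locus or open reading frame name. It adds every measured study target and, in each list described, the 2 members with the smallest p in each direction. Other members of a list were named only after their values were seen, as were CIRBP and the genes of symbol families.

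The procedure was tested on simulated arrays of all 53617 probe sets, with the 14884 genes then taken from that fit. It recovered 34% of genes changed by 0.5 log2 and 82% of genes changed by 1 log2. It called 119 genes in all, of which 3 were unchanged, and called 0 genes where no change had been made. The simulated noise was independent between probe sets, whereas genes vary together in the real arrays (estimated correlation 0.735 in the mitosis list). These rates therefore need not hold for the real arrays. The alternatives tried were the replicate number as a block, quantile normalization again, centring of arrays on their medians or on ribosomal protein genes, filters on dim probe sets, other variance moderation, array weights, fold thresholds, the mean of a gene's probe sets, other set tests, and leaving out each array in turn. Of these, 3 alternatives were added after seeing the data, and they concern repeated probe sets and a fit on the representative probe sets alone.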

Results

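The data compare gene expression in U-87 MG glioblastoma cells after 54 h of continuous exposure to targeted electromagnetic fields with that in unexposed cells, with 3 arrays per group. The fields were aimed at miR-381, mutated alpha-kinase 2, HSP70 and CHI3L1, and the comparison asks how the cells' transcripts differed after exposure. Array medians lay between 3.96 and 3.99 on the log2 scale. Correlations between arrays over all probe sets were 0.987 to 0.988 within exposed, 0.985 to 0.986 within unexposed and 0.982 to 0.987 between groups. Unexposed arrays were thus hardly more alike among themselves than arrays of different groups. The first principal component held 28.0% of the variance and separated the groups, with scores of 19.1 to 39.3 for exposed and -47.2 to -15.3 for unexposed arrays. Unexposed replicate 2 lay farthest out on it at -47.2. The second component held 20.5% of the variance, with unexposed replicate 1 at 53.1 and unexposed replicate 2 at -32.5. Because exposed cells grew in a box inside the Faraday chamber and unexposed cells in a box outside it, field and box cannot be told apart in any of the differences given here.

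Exposed cells had modest changes across many genes, with 208 genes higher and 248 lower than in unexposed cells. Among genes, the largest rise was that of RANBP3L, a relative of the Ran-binding protein RANBP3, at 8.88 ± 0.47 in exposed and 6.48 ± 1.04 in unexposed cells (SD, n = 3 each). Its log2 change was 2.40 (SE 0.47), or 5.29-fold, and 3.49-fold without unexposed replicate 2. The protocadherin PCDH18 rose by 1.57 (SE 0.20), and the secreted Wnt modulator SFRP2 rose by 1.28 (SE 0.21). Among genes that fell, the keratin-associated protein genes KRTAP2-3 and KRTAP1-5 changed by -1.20 (SE 0.15) and -1.14 (SE 0.12). They belong to a family of closely similar genes, so their signals are uncertain as to the member.

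Among the other genes that rose were the interleukin-36 receptor antagonist IL36RN (1.20), the bradykinin receptor BDKRB1 (1.18), the lysosomal tripeptidyl peptidase TPP1 (1.16) and HCFC1R1 (1.10). UBA7, the activating enzyme of the ubiquitin-like protein ISG15, rose by 1.06, the noncoding WFDC21P by 1.05 and the zinc finger gene ZNF404 by 1.04. TLR3, a sensor of viral RNA, rose by 1.03 and the small GTPase RHOB by 1.02. Among the genes that fell were the lysosomal protease CTSO (-1.03) and MYBL2 (-1.03), a transcription factor of cell cycle genes that went from 8.85 ± 0.27 to 7.82 ± 0.16. The centromere protein gene CENPU (-0.90) and the DNA repair helicase BRIP1 (-0.85) fell as well. The others were DCAF16 (-0.93), GCFC2 (-0.91), BLTP3A (-0.89), the RNA-binding PCBP3 (-0.87), the receptor GPR3 (-0.86) and IGFBP1 (-0.85), which binds insulin-like growth factors. For these 24 genes the SE lay between 0.09 and 0.47, and limma's Benjamini-Hochberg adjusted p between 0.0260 and 0.0432.

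**Figure D1:**
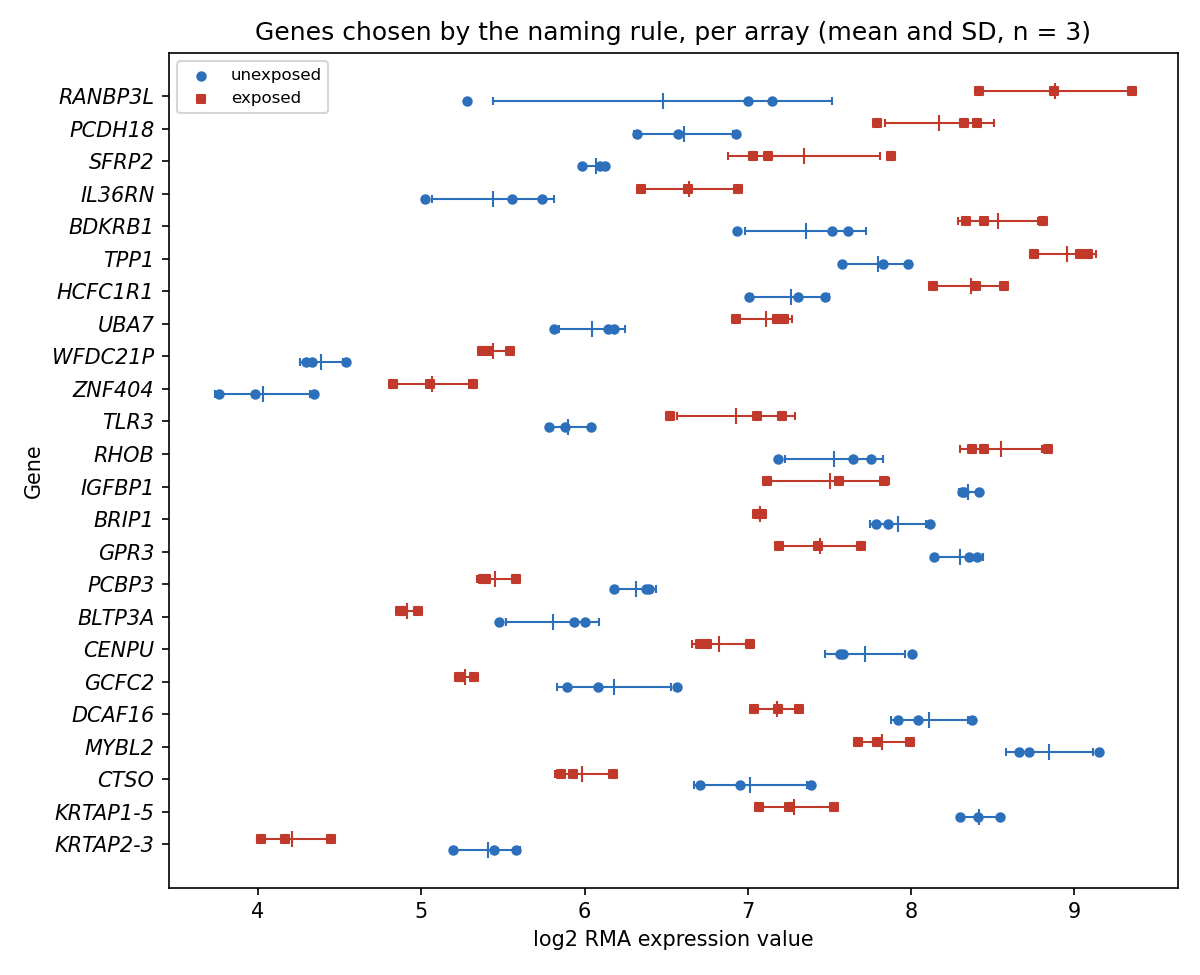
Log2 RMA expression value (horizontal axis) of the 24 changed genes taken by the naming rule (vertical axis), with 1 point per array (circles unexposed, squares exposed) and the mean ± SD of each group (n = 3). All exposed values of a gene lie on one side of its unexposed values, from RANBP3L, higher by 2.40 in exposed cells, to KRTAP2-3 with a change of -1.20.

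In all, 456 of 14884 genes changed in limma with Benjamini-Hochberg adjustment, 208 higher and 248 lower in exposed cells, with a median absolute log2 change of 0.50. Of these, 18 changed at least 2-fold, 13 upward and 5 downward, and these include LINC00641 (-1.25) and LINC03033 (1.35), noncoding genes named after their values were seen. Among all genes, 27.0% had exposed and unexposed values that did not overlap, where chance gives 10%. Over probe sets, 378 of 53617 changed, 185 higher and 193 lower, of which 198 were unnamed here. The other 180 carried a gene name, so most of the 456 genes did not pass when adjusted over all probe sets. RANBP3L, IL36RN, ZNF404, TLR3 and RHOB were among the genes that passed over genes alone. Among the changed genes 29 had more than 1 probe set, and for 6 of these a further probe set had the opposite sign. The gene count was 0 without exposed replicate 1, exposed replicate 2, unexposed replicate 2 or unexposed replicate 3, 67 without unexposed replicate 1 and 325 without exposed replicate 3, so the calls of all genes named in the report were lost in at least those 4 settings. Unadjusted p under 0.05 was reached by 2815 genes with all arrays and by 2065 to 2287 in those 4 settings. The count was also 0 without a mean-variance trend (2220 at an unadjusted p under 0.05), and 4, all higher, without variance moderation. It was 753 over probe sets above the median level, 1173 with the mean of a gene's probe sets, and 1209 with a fit on representative probe sets alone, which was chosen after seeing the data. With arrays centred on ribosomal protein genes, 66 genes changed, 23 higher and 43 lower, and the share of higher genes was 34.8% in place of 45.6%. The changes themselves hardly moved there, with a median over all genes of -0.0030 in place of 0.0029.

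Of the molecules the fields were aimed at, the genes of inducible HSP70 were the ones whose transcripts passed the threshold over all genes. HSPA1A (probe set 17026318) rose from 9.55 ± 0.07 to 10.1 ± 0.15 (SD, n = 3 each), a log2 change of 0.55 (SE 0.08, 1.47-fold, limma adjusted p = 0.0298). HSPA1B (probe set 17028007) rose by 0.53 (SE 0.08, limma adjusted p = 0.0298). These neighbouring genes are nearly identical in sequence and their values had a correlation of 0.993 over the 6 arrays, so the array does not separate them. CHI3L1 (probe set 16698185), a secreted glycoprotein of mesenchymal glioma, was at 8.88 ± 0.11 in exposed and 8.74 ± 0.11 in unexposed cells. Its change of 0.14 had an interval of -0.05 to 0.33 and did not pass (limma adjusted p = 0.430), and it was 0.0751 without exposed replicate 3. ALPK2 (probe set 16855545), whose mutation the array does not read, had a change of 0.33 with an interval of 0.08 to 0.59 (limma adjusted p = 0.145, and 0.0387 adjusted over the list alone). Without exposed replicate 2 its change was 0.21. The probe set named for MIR381 (16788756) was dim, at 2.66 ± 0.12 in exposed and 3.05 ± 0.12 in unexposed cells. Its change was -0.39 with an interval of -0.73 to -0.06 (limma adjusted p = 0.194), and it does not tell the mature microRNA from its precursor.

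Further HSP70 family members had positive values that did not pass over all genes: HSPA6 0.32, HSPA2 0.22, HSPA1L 0.18, HSPA4 0.17 and the mitochondrial HSPA9 0.02. With single arrays left out, HSPA6 was at 0.20 (without exposed replicate 1) and 0.17 (without unexposed replicate 3), HSPA2 at 0.0789 (without exposed replicate 2) and HSPA9 at -0.00652 (without exposed replicate 3). In the target list, 10 of 13 entries were measured, and HSPA5, HSPA8 and MIR381HG were not. Of the 10, 2 rose over all genes and 4 when adjusted over the list alone (HSPA1A, HSPA1B, HSPA4 and ALPK2). The study chose these molecules as its targets. With an array left out, 2 or 3 passed when adjusted over the list alone: HSPA4 was lost whichever of the 6 arrays was left out, and ALPK2 without exposed replicate 2 (0.0569) or any unexposed array (0.0769 to 0.0879). The list as a whole was shifted upward by camera (adjusted p = 0.00106), and adjusted p = 0.130 with an estimated correlation. That list counts HSPA1A and HSPA1B as separate genes, though the array does not separate them. Over probe sets, 9 of the 22 that carry a target's name changed, all of them HSPA1A or HSPA1B. These 9 are not independent: the HSPA1A probe sets 17026318, 17027994 and 17030820 hold the same values. The number of targets past the threshold was 2 without exposed replicate 3 and 0 without any other array, with limma adjusted p of HSPA1A up to 0.120. It was also 0 without a mean-variance trend, without variance moderation and with arrays centred on ribosomal protein genes, a setting in which the HSPA1A change was 0.55 (limma adjusted p = 0.110).

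**Figure D2:**
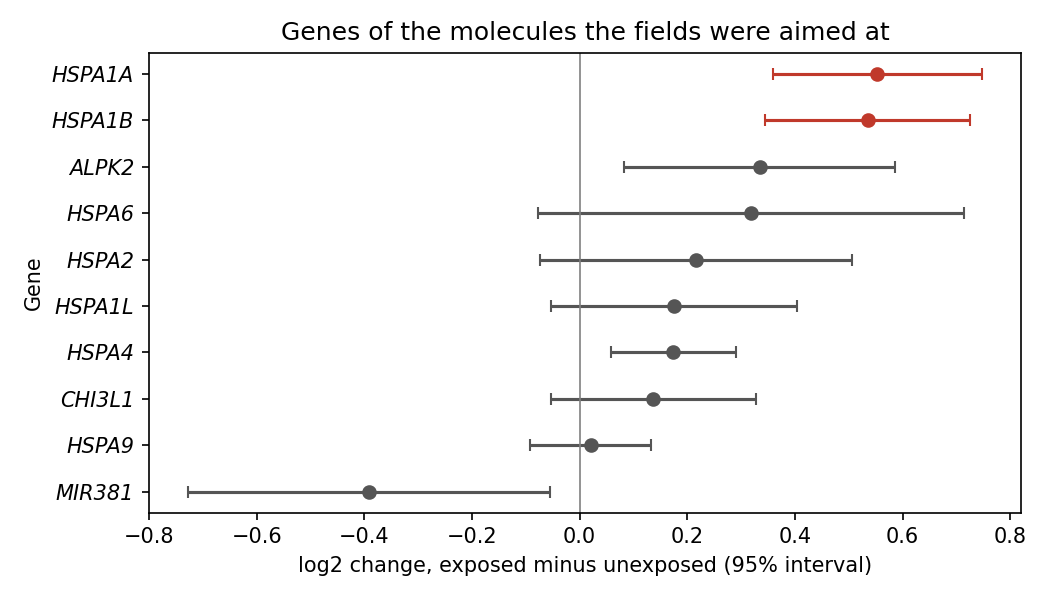
Log2 change, exposed minus unexposed (horizontal axis), of the 10 measured genes of the molecules the fields were aimed at (vertical axis), as points with 95% intervals from 3 arrays per group. HSPA1A (0.55) and HSPA1B (0.53), drawn in red, passed the threshold over all genes, and MIR381 (-0.39) was the gene with a negative value.

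Among 23 measured mitosis and G2/M genes, 11 fell in exposed cells, all 23 had negative values, and 19 fell when adjusted over the list alone. The list was shifted downward by camera (adjusted p = 3e-17), and adjusted p = 0.271 with an estimated correlation, which was 0.735 for this list. The list's median log2 change was -0.47, and its mean level went from 8.85 ± 0.10 in unexposed to 8.42 ± 0.15 in exposed cells (SD, n = 3 each). MKI67, the proliferation marker Ki-67, changed by -0.60 (SE 0.09) and PRC1, which bundles spindle microtubules, by -0.57 (SE 0.09), both with limma adjusted p = 0.0298. Named after their values were seen, the spindle motor KIF11 (-0.63), the cyclin CCNB2 (-0.59), CDK1 (-0.58), BUB1B (-0.52), CENPA (-0.52), PLK1 (-0.50), KIF23 (-0.47), TOP2A (-0.46) and CDC20 (-0.41) fell too.

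Of 23 measured DNA replication and S-phase genes, 7 fell, all 23 had negative values, and 19 fell when adjusted over the list alone, with a median of -0.36. Camera gave this list an adjusted p of 7.64e-15, and adjusted p = 0.271 with an estimated correlation. E2F1, a transcription factor that drives entry into S phase, changed by -0.38 (SE 0.06), and CDC45, a part of the replicative helicase, by -0.52 (SE 0.09). The others, named after their values were seen, were the cyclin CCNE2 (-0.76), the helicase subunits MCM3 (-0.55) and MCM2 (-0.30), the licensing factor CDT1 (-0.47) and UHRF1 (-0.28). With each array left out in turn, the median over both lists lay between -0.46 and -0.33.

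In the cytosolic heat shock list, 8 of 21 entries were measured, and DNAJB1 and HSP90AA1 were not. Of the 8, 4 rose in exposed cells, 4 did not pass, and 5 rose when adjusted over the list alone. The list was shifted upward by camera (adjusted p = 5.48e-05), and adjusted p = 0.252 with an estimated correlation. HSPB1, a small heat shock protein, rose by 0.60 (SE 0.09, limma adjusted p = 0.0298) and HSPH1, a nucleotide exchange factor of HSP70, by 0.55 (SE 0.09, limma adjusted p = 0.0334). HSPA4L (0.46) and the co-chaperone BAG3 (0.28) also rose and were named after their values were seen, as was HSF1, the transcription factor of the response, at 0.29 (limma adjusted p = 0.0868). CHORDC1, with a change of -0.07, was the member with a negative value, and it was at 0.19 without exposed replicate 2 and 0.10 without unexposed replicate 3. In the unfolded protein response list of the endoplasmic reticulum, 9 of 19 entries were measured, and HSPA5 and HSP90B1 were not. All 9 had positive values and 3 rose. When adjusted over the list alone 6 rose, but 3 without exposed replicate 1 and 4 with any other array left out. This list was shifted upward as well (camera adjusted p = 1e-06), and adjusted p = 0.0990 with an estimated correlation. The 3 were the calcium-binding chaperone CALR (0.30, SE 0.05), MANF (0.63, SE 0.10) and, named after its values were seen, HYOU1 (0.48).

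Of 8 measured metallothionein and zinc genes, MT1F rose by 0.51 (SE 0.09) and the rest did not pass. The list was shifted upward by camera (adjusted p = 0.00128), and adjusted p = 0.194 with an estimated correlation. When adjusted over the list alone 4 genes rose, and 1 without exposed replicate 1, exposed replicate 2 or unexposed replicate 2. MT1M had a change of 0.47 (limma adjusted p = 0.0941) and MT1X one of -0.02 (0.0114 with quantile normalization again, 0.0174 without exposed replicate 2 and 0.0288 without unexposed replicate 1), and these genes are similar enough in sequence for their signals to be uncertain. Of 24 p53 targets in the list 13 were measured, and CDKN1A and MDM2 were not. Of the 13, 3 rose and 10 did not pass, and 4 rose when adjusted over the list alone. These too were shifted upward as a list (camera adjusted p = 0.000328), and adjusted p = 0.130 with an estimated correlation. EDA2R, a receptor of the tumour necrosis factor family, rose by 0.76 (SE 0.08, limma adjusted p = 0.0260) and the stress cytokine GDF15 by 0.91 (SE 0.15). SPATA18 (0.83) rose too, and TP53I3 had a change of 0.86 (limma adjusted p = 0.0599), both named after their values were seen. CCNG1 (-0.16, and -0.0918 without unexposed replicate 2) and BAX (-0.10, and -0.0616 without exposed replicate 2 and -0.0432 without unexposed replicate 1) did not pass.

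Of 18 measured genes of the type I interferon response, 3 rose in exposed cells and 15 did not pass. When adjusted over the list alone 8 rose, and 6 without exposed replicate 1. As a list they were shifted upward by camera (adjusted p = 5.05e-06), and adjusted p = 0.0990 with an estimated correlation. IFIH1 and RIGI, sensors of viral RNA, rose by 0.87 (SE 0.14) and 0.52 (SE 0.08), with limma adjusted p of 0.0298 and 0.0312. XAF1 rose by 0.83, and IFIT1 went from 3.37 ± 0.07 to 4.37 ± 0.59 without passing (limma adjusted p = 0.0926), both named after their values were seen. IFI44 (-0.07) and the chemokine CXCL10 (-0.12) were the members with negative values, which were 0.00910 without exposed replicate 1 for IFI44 and 0.17 without exposed replicate 2 for CXCL10. The list's mean level was 5.37 ± 0.03 in exposed and 5.01 ± 0.03 in unexposed cells (SD, n = 3 each). Some members were dim: in unexposed cells IFIH1 stood at 4.16, near the array medians of 3.96 to 3.99, and IFIT1 and CXCL10 stood below them.

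Of 12 measured circadian clock genes, PER2 fell in exposed cells and the other 11 did not pass. The list was shifted downward by camera (adjusted p = 0.00106), and adjusted p = 0.130 with an estimated correlation. PER2, a repressor within the clock, changed by -0.67 (SE 0.09, limma adjusted p = 0.0287). When adjusted over the list alone 6 genes fell, and 3 without exposed replicate 3, unexposed replicate 2 or unexposed replicate 3. The transcription factor HLF had a change of -0.70 (limma adjusted p = 0.0579), while DBP was at 0.20 and BMAL1 at 0.00236, the latter at -0.00971 with arrays centred on their medians and at -0.00356 with arrays centred on ribosomal protein genes. With each array left out in turn BMAL1 lay between -0.0561 and 0.0976. Cytosolic ribosomal protein genes, used by every cell for translation, were shifted slightly downward by camera (adjusted p = 0.0174), with adjusted p = 0.663 with an estimated correlation and 0.270 by fry. Their median was -0.10 over 29 measured members, of which 0 passed by limma, 3 had an unadjusted p under 0.05 and 24 had negative values. RPS19 was at 0.23, RPL11 at -0.22 and RPL12 at -0.20. The list did not pass without exposed replicate 2 (camera adjusted p = 0.248) or without unexposed replicate 2 (0.101), and over all its alternatives the adjusted p ran from 0.00356 to 0.663.

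**Figure D3:**
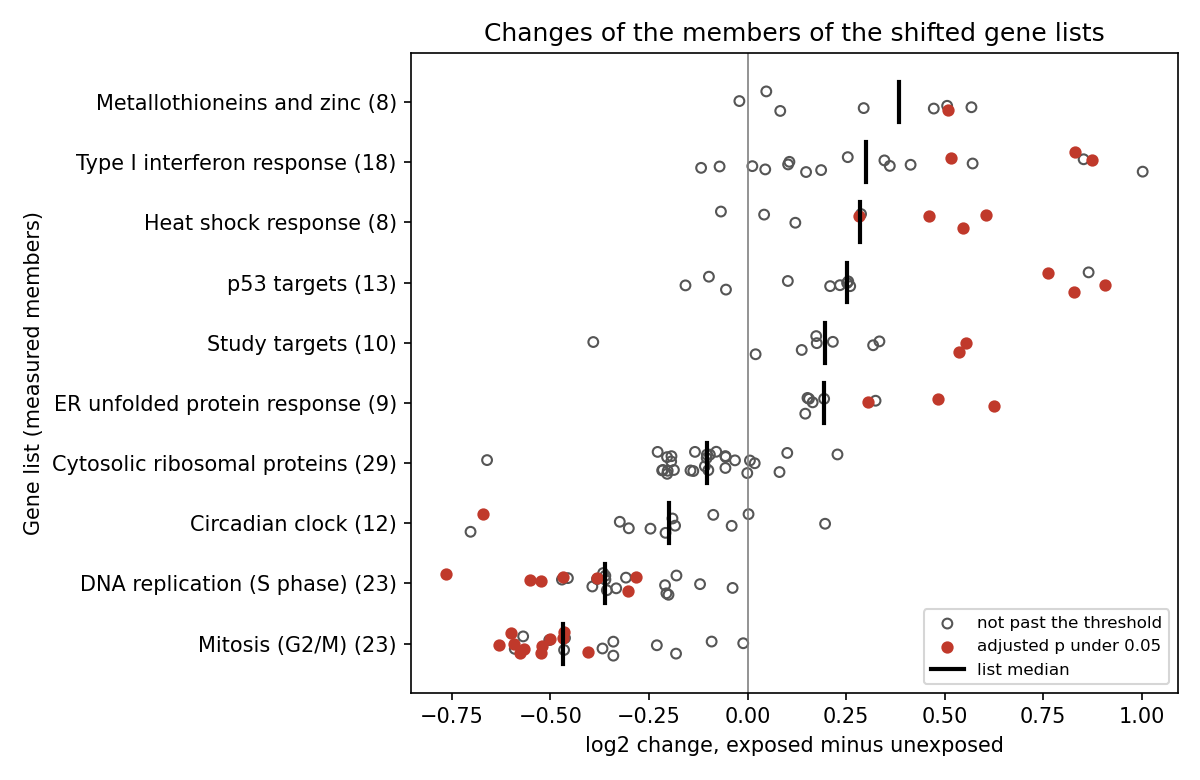
Log2 change, exposed minus unexposed (horizontal axis), of each measured member of the 10 gene lists shifted by camera at its preset correlation (vertical axis). Points are genes, filled where the gene itself passed the threshold, and bars mark list medians, from -0.47 for mitosis to 0.38 for metallothioneins.

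In all, 10 of the 35 tested lists were shifted by camera, 6 upward and 4 downward. With an estimated correlation 0 were, while 6 had an unadjusted p under 0.05, and fry called 14.

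With all 6 arrays, no list of markers of other cell types passed by camera. None of the measured markers of leukocytes and microglia (5 genes, camera adjusted p = 0.172), endothelium (8 genes, 0.938), epithelium (10 genes, 0.930), oligodendrocytes (7 genes, 0.844) or astrocytes (8 genes, 0.495) passed over all genes in limma, and 4 of these genes had an unadjusted p under 0.05. The same held for 13 mesenchymal and 16 proneural glioma markers (camera adjusted p = 0.912 and 0.938), of which 5 had an unadjusted p under 0.05. Of 7 neuronal markers the microtubule protein gene MAP2, named after its values were seen, rose by 0.91 (SE 0.12), and the list did not pass (camera adjusted p = 0.0553). It did without exposed replicate 3 (0.0482) or unexposed replicate 3 (0.0225), with arrays centred on ribosomal protein genes (0.0319), above the median level (0.0320), with the mean of a gene's probe sets (0.0416) and by fry (0.0173), with a range of 0.0173 to 0.271 over its alternatives. In the imprinted region that holds MIR381, BEGAIN was lower by a log2 change of -0.63 (limma adjusted p = 0.0432), also named after its values were seen, and the other 5 of 6 measured genes did not pass (camera adjusted p = 0.553, fry adjusted p = 0.0358). The reported miR-381 targets LRRC4 (-0.11) and WEE1 (-0.11) did not pass, and as a list of 2 they were not tested. The 15 voltage-gated calcium channel genes and 13 histone genes of the fixed lists had 0 named probe sets here.

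The lists that follow were not shifted by camera, and the genes given for them were named after their values were seen. In the list of targets of NRF2, the regulator of antioxidant genes, the heme oxygenase HMOX1 rose by 0.70, while 10 of 11 measured members did not pass (camera adjusted p = 0.565). When adjusted over that list alone 1 gene rose and 2 fell, and at an unadjusted p under 0.05 by limma 1 was higher and 4 were lower. HMOX1 thus does not stand for the list. The hypoxia list held the carbonic anhydrase CA12 (0.43, camera adjusted p = 0.229) and the lipid synthesis list the fatty acid desaturase SCD (0.66, camera adjusted p = 0.938), both higher. The matrix proteoglycan LUM rose by 0.83 among 11 measured matrix genes, whose median was -0.07 and mean 0.07 (camera adjusted p = 0.991). No collagen gene of that list was measured. The collagenase MMP1 changed by -0.78 among 10 protease and invasion genes, with a median of 0.06 and a mean of -0.03 (camera adjusted p = 0.596). The median and mean also differed in sign for lipid synthesis (-0.02 and 0.02) and endothelial markers (0.06 and -0.01). Among YAP targets FJX1 (-0.68) and DLC1 (-0.46) fell (camera adjusted p = 0.161, fry 0.0137), among apoptosis regulators BIRC2 (-0.43) fell (camera 0.431, fry 0.0120), and among calcium handling genes ORAI3 (0.43) rose (camera 0.415). The lists of the ATF4 amino acid response (camera adjusted p = 0.844), TGF-beta response (0.565), autophagy and lysosome (0.508) and oxidative phosphorylation (0.522) held no gene past the threshold by limma, with 2, 2, 3 and 4 genes at an unadjusted p under 0.05. Of 37 entries in the oxidative phosphorylation list 11 were measured, and no NDUF, SDH or ATP5 gene was.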

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

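The fit on representative probe sets alone and the settings that count repeated values once were chosen after seeing the data. All 456 changed genes kept their sign in every setting they were tested in, which is no evidence of robustness. All exposed values of each lay on one side of its unexposed values, so leaving out an array could not reverse it. The block, the trend and the variance moderation do not alter the log2 change. The number past the threshold moved with the error model, the scaling and the arrays used. The numbers 1 to 3 do not pair the arrays: deviations of same-numbered arrays had correlations of -0.0164, -0.0253 and 0.00964, and 1 of 6 arrays correlated best with its own number. With the replicate block there were 0 changed probe sets, 0 genes (2286 at an unadjusted p under 0.05) and 0 targets in limma, and 10 lists. Without a mean-variance trend the counts were also 0, 0 (2220 unadjusted) and 0, and without variance moderation 4 probe sets, 4 genes (2649 unadjusted) and 0 targets, the 4 genes being PPIB, PPID, GAS6-DT and MCHR2-AS1, named after their values were seen. With arrays centred on ribosomal protein genes, 185 probe sets, 66 genes (63 among the 456) and 0 targets passed. The changes themselves hardly moved (HSPA1A 0.553 and 0.547), so the calls were lost through the error estimate and not through smaller changes. Counts were higher over brighter probe sets, with 1320 probe sets and 753 genes above the median level and 599 probe sets above log2 of 5. These filters change both the number of tests and the variance moderation, and the 2 were not separated. Array weights gave 568 probe sets. With at least a 2-fold change 52 probe sets and 18 genes passed, and with unadjusted p in its place 23 genes. The fit on representatives alone gave 1209 genes. It kept the log2 changes and the 14884 genes of the main fit, so the higher count came from variance moderation estimated without the other probe sets. The mean of a gene's probe sets gave 1173 genes. There the values of genes with several probe sets changed as well, and the cause was not tested. With an array left out, 0 to 257 probe sets, 0 to 325 genes and 0 to 2 targets passed, with fewer arrays to estimate the spread, and 9 to 12 lists. An estimated correlation left 0 of 10 lists and fry called 14. For lists there is no value with robust or without moderation, since camera has no such setting.

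Of the 115 single genes followed, 82 passed. All 82 lost the call with the block, without trend and without moderation, 46 did with arrays centred on ribosomal protein genes, 7 with arrays centred on their medians and 1 each with array weights and quantile normalization. The genes that changed sign had small values that never passed. MT1X was at 0.0114 with quantile normalization again, and BMAL1 at -0.00971 with arrays centred on their medians, -0.00356 with ribosomal protein genes and -0.0191 with array weights. With an array left out the ranges were -0.0561 to 0.0976 for BMAL1, -0.24 to 0.19 for CHORDC1, -0.35 to 0.17 for CXCL10, -0.00652 to 0.0459 for HSPA9, -0.20 to 0.00910 for IFI44 and -0.0797 to 0.0288 for MT1X. The arrays carry no measure of signal over background here, so how far dim genes such as MIR381 rise above background is not known.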

Other observations

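Signalling genes that respond within minutes to serum or stress went in both directions in exposed cells. Of 21 measured immediate early genes, FOS rose by 0.59 (SE 0.11) while the feedback inhibitors of receptor signalling SPRY4 and SPRY2 changed by -0.50 (SE 0.07) and -0.49 (SE 0.08), with limma adjusted p of 0.0344, 0.0288 and 0.0298. JUNB had a change of 0.51 without passing (limma adjusted p = 0.0510), and 8 genes rose and 4 fell when adjusted over the list alone (3 and 3 without exposed replicate 2). The list did not pass (camera adjusted p = 0.104), but did with arrays centred on ribosomal protein genes (0.0291), without unexposed replicate 1 (0.0492) or without unexposed replicate 3 (0.0398), and its adjusted p over all alternatives ran from 0.0291 to 0.663. Among 15 growth factor receptor and glioma driver genes, EGFR changed by -0.30 (SE 0.05, limma adjusted p = 0.0348) and KDR had a value of -0.43, RB1 one of 0.24 and IGF1R one of 0.18, none of the latter 3 passing. That list had a camera adjusted p of 0.104 and a fry adjusted p of 0.0116.

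Among 16 cholesterol synthesis genes the sterol demethylating enzyme MSMO1 rose by 0.69 (SE 0.08) and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, changed by -0.43 (SE 0.08). DHCR7 had a value of 0.36 and ACAT2 one of -0.41, neither passing over all genes, and 4 genes rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.565). Among 13 inflammatory targets of NF-kappaB, the chemokine CCL2 rose by 0.70 (SE 0.13) and the cytokine IL11 changed by -0.55 (SE 0.08), while NFKB1 (0.25) and CXCL8 (-0.23) did not pass (camera adjusted p = 0.555). Among 233 families of at least 8 genes that share a symbol stem, tested after the data were seen, 7 were shifted by camera and 0 with an estimated correlation (adjusted p = 0.974). The small noncoding SNAR family stood highest, with a median of 0.40 over 8 genes that are nearly identical in sequence and of which SNAR-H rose by 0.75. The others were HSPA and MT upward and MCM, KIF, HNRNPA and NUP downward, and among 40 kinesin (KIF) genes 8 fell.

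Of the tests that follow, those on level-dependent bias, on a single aberrant array and on the number of changed probe sets over other splits were chosen after the results they concern were seen. The 6 arrays can be divided into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real division gave 378 probe sets, 456 genes and 10 lists, and the highest count of any other was 0 probe sets, 0 genes (with 562 at an unadjusted p under 0.05 in limma) and 4 lists, so that 1 of the 10 divisions reached each real count. Every other division mixes exposed and unexposed arrays, so a difference between the groups adds to its spread and lowers its count. The low counts of the other divisions are therefore no fair measure of chance.

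The lower level of the mitosis and DNA replication lists was set against explanations from the arrays. Over the 46 mitosis and DNA replication genes the median log2 change was -0.39, while 95% of 10000 random lists of the same size and matched expression level lay between -0.10 and 0.04, which argues against a bias that depends on level. With an array left out the weakest median was -0.33 (without exposed replicate 2), which argues against a single aberrant array. A lower rate of division in exposed cells is a candidate explanation, and whether it came from the field, from the box inside the chamber or from a difference in cell density was not tested.

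HSPA1A and HSPA1B rose in exposed cells, and CIRBP, a cold-inducible RNA-binding protein gene singled out after its values were seen, fell, at 7.98 ± 0.20 against 8.73 ± 0.08 in unexposed cells (log2 change -0.75, SE 0.10, limma adjusted p = 0.0287). The cytosolic heat shock list, which holds neither HSPA1A nor HSPA1B, had a median of 0.29 over 8 genes, against -0.17 to 0.13 for 95% of level-matched random lists, which argues against a bias that depends on level for that list. A slightly warmer exposed box could raise heat shock genes and lower cold-inducible ones. The planned test used RBM3, the other cold-inducible gene of this kind, but 0 probe sets carried its name here, so a warmer box and an effect of the field cannot be told apart.

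The clock list had a median of -0.20 over 12 genes, against -0.15 to 0.11 for 95% of level-matched random lists, which argues against a bias that depends on level. For groups sampled at different circadian phases, the prediction set in advance was that the PER, CRY, DBP and TEF arm would move against BMAL1, NPAS2 and CLOCK. The arms' mean changes were -0.19 (SE 0.03) and -0.13 (SE 0.04), a difference of -0.0585 (exact permutation p = 0.717, two-sided). That permutation exchanges genes between the arms, so it does not measure the spread between arrays. Both means lay below the bound of -0.1 set in advance for excluding a phase shift. The second lay within its SE of that bound, a condition that was not part of the rule. With that margin, a difference in phase cannot be told apart from a lower level of the whole list. BMAL1 itself was at 0.00236, so the negative mean of its arm came from NPAS2 and CLOCK. An effect of the exposure remains open and untested.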
